A study of Mus musculus with 8 samples.

How the data were processed

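The samples were mouse skin wounds from Sm22-Cre;tdTomato animals of mixed background, dissociated with collagenase, from which viable tdTomato-high cells were sorted at 12, 15, 21 and 26 days post wounding. RNA was made into SMART-seq2 libraries, with 2 libraries per day. Nothing in the labels says that the libraries of a day came from separate animals, so the p-values measure the spread between these libraries and no more. The depth of sequencing is unknown, since TPM keep none, and no interval for counting error could be computed.

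The table of all genes deposited by the authors holds a signal per gene and library for 43346 genes, with Ensembl gene identifiers and gene types. Per column, the values minus 1 summed to 1000000 and no value was under 1, so the deposited signal was read as TPM plus 1, and 1 was subtracted to obtain TPM. The submitters' processing notes name RSEM 1.12.2 and the genome mm10, and the aligner and the transcript annotation are not given in the sources used here. SMART-seq2 does not keep the strand, so overlapping genes on opposite strands cannot be told apart, and the share of reads between paralogs or pseudogenes is uncertain. In 128 gene entries the symbol is listed more than once, and genes were followed by identifier. The value columns carry the day and a number that differs from the replicate numbers of the labels, so columns were assigned to days, not to single samples, and the columns could not be paired by the labels. The authors' tables of clusters C1 to C5 give, per the file headers, a p-value for each of 4120 genes, all under 0.05, whose test and adjustment are not stated. The 40 value columns per sample in those tables were not used here.

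TPM were taken to log2(TPM + 1), and genes with at least 1 TPM in at least 2 libraries were tested, 15062 in all. A log2 change on this scale understates the fold of genes with few TPM. The limma trend method was fitted with day as a factor over all 8 libraries (residual degrees of freedom 4, prior degrees of freedom 4.76), with an F test over the 4 days and 2-sided contrasts of day 15 against 12, 21 against 15, 26 against 21 and 26 against 12. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and an adjusted p under 0.05 counted as passed. Rose, fell, higher and lower refer to genes that passed. The contrasts that share a day share its libraries and are not independent.

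Before the data were examined, 24 gene lists were fixed, and the comparisons, the tests, the alternatives and the rule for naming genes were chosen. The lists covered contractile, matrix, matrix protease, TGF-beta, BMP, Wnt, Hedgehog, adipogenic regulator, adipocyte, brown and beige fat, cell division, inflammatory, complement and interferon, dermal fibroblast lineage, dermal papilla and dissociation stress genes, and markers of macrophages and leukocytes, lymphocytes and granulocytes, endothelium, keratinocytes, pericytes and smooth muscle, skeletal muscle, Schwann cells and melanocytes, and red cells and platelets. The 23 lists with at least 5 tested genes were tested with camera of limma at a preset inter-gene correlation of 0.01, with adjustment over the 92 tests of lists and contrasts. With a correlation estimated from the libraries, none of these tests passed. Counts of members past the test are given with adjustment over all tested genes and adjusted over the list alone. The direction of each list median was checked under each scaling; medians near 0 changed sign between scalings for several lists, and such a case is stated where a median is used.

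By the rule for naming genes, each contrast names the 5 genes with the largest rise and the 5 with the largest fall among genes that passed, whose libraries did not overlap between the days and whose mean level was at or above the median of tested genes, leaving out marker genes, small RNAs and gene models with symbols of the Gm, Rik or LOC kind or with accession prefixes such as AI or BC. Symbols of other kinds, such as RP24-317P24.2 and AY036118, were kept. It also names up to 4 members of each list that passed, by adjusted p, or the 2 with the lowest p where none passed, and always Tagln, Acta2, Pparg, Zfp423, Fabp4, Adipoq, Bmpr1a, Bmp4 and Tgfbr2. Some genes picked by the rule are not reported here, although counts over the rule include them. Genes named outside the rule were chosen after their values were seen, among them Xist, the collagen genes of the share of TPM, Cidec, Lep, Ucp1, and members of the lists added later. The added lists, likewise chosen after results were seen, held imprinted genes, interferon-inducible GTPases, ribosomal proteins, cholesterol metabolism, glycolysis, Y-linked genes and a second list each for keratinocytes and for macrophages.

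The share of each list in each authors' cluster was tested with a 2-sided Fisher's exact test against the tested genes, adjusted over 115 pairs. Similarity of libraries was measured by Pearson's r and by principal components of log2(TPM + 1). The alternatives chosen beforehand were quantile normalization, a pseudocount of 0.1, no filter on low values, a filter at 10 TPM, sample weights, a fit of the 2 days of a contrast alone, an estimated inter-gene correlation, all genes as background for the clusters, the 1000 most variable genes for similarity, and leaving out each library in turn. Added after seeing the data were median-ratio scaling on genes with at least 10 TPM in every library, protein-coding genes alone, leaving out the pair of libraries with the most Xist, the level of Xist or of 4 Y-linked genes as a covariate, and the number of the value column as a block. Where leaving out a library left a day with 1 library, limma assumed that the lone library varied like the others. The sample weights came out equal for the 2 libraries of each day. They therefore weighed days against each other and could not weigh down 1 library of a day.

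The fit was tested on simulated data with the residual spread of the tested genes, in which 200 genes were given a known change in each contrast. At a log2 change of 1 it recovered 22%, 17%, 22% and 20% of the changed genes in the order of the contrasts above, and at a log2 change of 2 it recovered 77%, 72%, 71% and 64%. False calls were 3 of 102, 7 of 96, 0 of 93 and 3 of 87, and for day 26 against day 12, the contrast in which this was run, camera gave a p under 0.05 for 2% of 200 random lists of 20 genes. The simulated genes varied independently of each other. That rate therefore says nothing about lists whose genes vary together, such as the cell division genes (estimated correlation 0.581) or pericyte and smooth muscle markers (0.946). Gene positions were taken from GENCODE vM21 by identifier, whose release may differ from the authors' annotation. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.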

Results

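RNA was sequenced from cells that carried a red fluorescent label and were sorted from healing mouse skin. Cells of the Sm22-Cre;tdTomato strain carry tdTomato after activity of the Sm22 promoter, a promoter of contractile cells such as myofibroblasts. Viable tdTomato-high cells were taken from wounds at 12, 15, 21 and 26 days post wounding, and 2 SMART-seq2 libraries (full-length cDNA from little RNA) were held for each day, 8 in all. The series concerns how wound fibroblasts change towards the time at which new fat cells form in the wound, so each later day was compared with an earlier one. The values were TPM (transcripts scaled to a fixed sum per library) for 43346 genes. TPM keep no record of depth, so the depth of each library is unknown and no counting interval could be given. Between 13135 and 14147 genes reached 1 TPM per library. Levels are given below as mean ± SD in TPM over the n = 2 libraries of a day, and log2 changes with their SE from the limma fit over all 8 libraries. Library numbers are those of the authors' value columns. Positions are from GENCODE vM21 on GRCm38 (mm10), in which 155 of the 158 gene identifiers looked up were found.

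The genes followed most closely have these identifiers and positions. Acta2 (ENSMUSG00000035783.8) lies on chromosome 19 from 34241090 to 34255590. Tnn (ENSMUSG00000026725.13) lies on chromosome 1 from 160085029 to 160153580. Cyp2f2 (ENSMUSG00000052974.7) lies on chromosome 7 from 27119909 to 27133660. Zfp423 (ENSMUSG00000045333.11) lies on chromosome 8 from 87661810 to 87959595. Wisp2 (ENSMUSG00000027656.7) lies on chromosome 2 from 163820861 to 163833146. Mmp3 (ENSMUSG00000043613.7) lies on chromosome 9 from 7445822 to 7455975. H19 (ENSMUSG00000000031.11) lies on chromosome 7 from 142575529 to 142578143. Igf2 (ENSMUSG00000048583.12) lies on chromosome 7 from 142650766 to 142666816. Tagln (ENSMUSG00000032085.4) lies on chromosome 9 from 45929619 to 45936058. Tnc (ENSMUSG00000028364.11) lies on chromosome 4 from 63959785 to 64047015. Dkk2 (ENSMUSG00000028031.5) lies on chromosome 3 from 132085292 to 132180304. Bmp4 (ENSMUSG00000021835.10) lies on chromosome 14 from 46383520 to 46390669. Pparg (ENSMUSG00000000440.8) lies on chromosome 6 from 115360951 to 115490399. Adipoq (ENSMUSG00000022878.5) lies on chromosome 16 from 23146536 to 23158028. Krt5 (ENSMUSG00000061527.6) lies on chromosome 15 from 101707070 to 101712898. Spp1 (ENSMUSG00000029304.10) lies on chromosome 5 from 104435118 to 104441050.

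The libraries lay in the order of the days on the first principal component. Across the 15062 tested genes Pearson's r averaged 0.975 between the libraries of a day and 0.95 between libraries of different days, although the lowest value within a day (0.969) was below the highest between days (0.978). Genes are not independent replicates, so no p-value is attached to these correlations. The first component held 43.4% of the variance, the second 17.3% and the third 13.1%. The second set day 21 (33.4 and 39.4) apart from the other days (0.476 and below), and on the third library 1 of day 15, the library with the most Xist, stood at 42.3 against -10.7 for the other library of that day. Abundant matrix transcripts, Col1a1, Col1a2, Col3a1 and Sparc, together took 5.56% and 7.33% of all TPM in the libraries of day 12, 7.47% and 8.12% on day 15, 12.5% and 10.7% on day 21, and 15.0% and 13.6% on day 26. Xist, the RNA of the inactive X chromosome in female cells, differed between libraries of the same day, with 30.7 and 5.54 TPM on day 15, 4.78 and 27.5 TPM on day 21, and at most 0.01 TPM in the libraries of days 12 and 26. The steps from day 12 to day 15 and from day 21 to day 26 thus set libraries almost without Xist against libraries with it. Sex of the animals and day cannot be told apart in these steps. The pair of libraries with the most Xist held library 1 of day 15 and 1 library of day 21. Fits without this pair kept 1 library on each of these days, so they cannot separate sex from the loss of libraries.

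**Figure D1:**
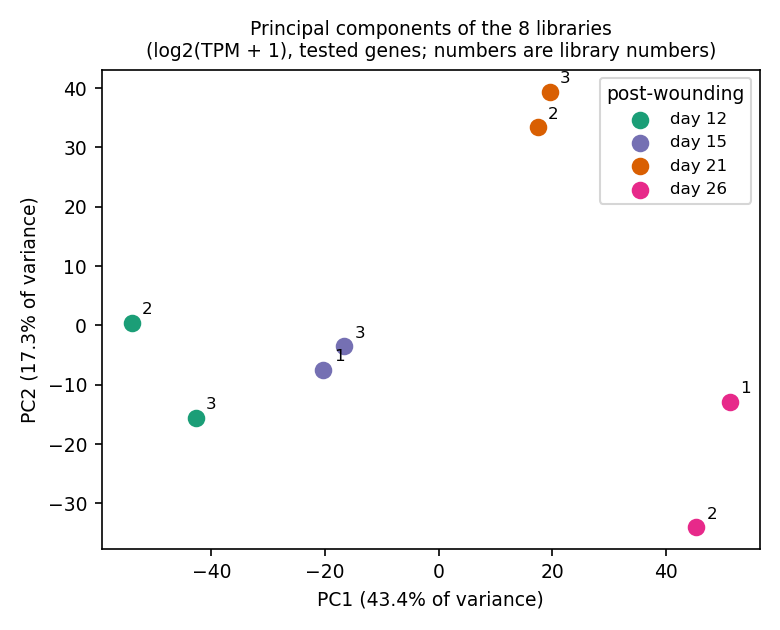
Principal components of the 8 libraries, computed on log2(TPM + 1) of the tested genes, with the share of variance on each axis, 1 point per library, coloured by day and numbered as in the authors' columns. The first component (43.4% of the variance) runs from the libraries of day 12 at -54.1 and -42.8 to those of day 26 at 51.3 and 45.4.

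Between day 12 and day 26, many genes of contraction and of cell division fell, while several genes of the matrix, of Wnt signalling and of chemokines rose. Acta2, which encodes smooth muscle actin and marks myofibroblasts, went from 1481 ± 181 to 513 ± 186 TPM (log2 change -1.57, SE 0.34, adjusted p = 0.0156). Tnn, which encodes the matrix protein tenascin N, fell the most of the genes named, from 163 ± 49 to 3.69 ± 0.573 TPM (log2 change -5.10, SE 0.29, adjusted p = 6.16e-05). Cyp2f2, which encodes a cytochrome P450 enzyme, rose from 3.09 ± 0.283 to 457 ± 57.6 TPM (log2 change 6.80, SE 0.35, adjusted p = 4.05e-05). Zfp423, a transcription factor of preadipocytes, rose from 4.24 ± 0.445 to 12.7 ± 3.95 TPM (log2 change 1.36, SE 0.27, adjusted p = 0.0113). Other large rises were those of the secreted protein gene Wisp2, from 54.4 to 1180.2 TPM, the matrix protease gene Mmp3, from 97.5 to 2015 TPM, and the lymphoid chemokine gene Ccl19, from 2.69 to 68.5 TPM. Among the falls were the imprinted genes Mest, from 589.5 to 23.7 TPM, H19, from 182 to 6.96 TPM, and Igf2, from 141 to 6.21 TPM. Rps2-ps10, a pseudogene whose reads cannot be told with certainty from those of its parent gene, went from 178 ± 31 to 17.6 ± 22.8 TPM, and Lgals7, a galectin of stratified epithelium, from 2.21 ± 2.10 to 81.3 ± 40.5 TPM.

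Of the contractile genes 13 of 20 tested fell and 7 did not pass (16 fell adjusted over the list alone), with a median log2 change of -1.08, or -0.88 relative to the median of all tested genes (camera adjusted p = 4.24e-08, and adjusted p = 0.395 with an estimated correlation). The actin gene Actg2 went from 211 ± 9.12 to 35.7 ± 1.14 TPM, the actin-binding Cnn1 from 12.4 ± 2.24 to 0.635 ± 0.318 TPM, and the focal adhesion gene Zyx from 199.6 ± 3.73 to 45.9 ± 7.65 TPM. Tagln, also called Sm22, the gene whose promoter drives Cre in this strain, had 214 ± 56 TPM on day 12 and 103 ± 53.8 TPM on day 26. It did not pass (log2 change -1.13, adjusted p = 0.0599). Of the cell division genes 26 of 29 tested fell and 3 did not pass (29 fell adjusted over the list alone). The cell division median was -1.94 (camera adjusted p = 1.59e-16, and adjusted p = 0.395 with an estimated correlation). Birc5, a regulator of mitosis, went from 59.8 ± 5.33 to 8.81 ± 1.65 TPM, the cyclin gene Ccna2 from 44.1 ± 3.92 to 6.03 ± 1.0 TPM, and the mitotic kinase gene Plk1 from 26.5 ± 1.20 to 2.50 ± 0.834 TPM.

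Of the matrix genes 12 of 27 tested rose, 4 fell and 11 did not pass (12 rose and 5 fell adjusted over the list alone). The matrix median was 0.26 (camera adjusted p = 0.00153, and adjusted p = 0.684 with an estimated correlation). Dcn, which encodes the small proteoglycan decorin, rose from 2979 ± 246 to 10351 ± 1269 TPM and its relative Fmod from 92.9 ± 0.94 to 277 ± 74.9 TPM, whereas Tnc, the gene of the wound matrix protein tenascin C, fell from 213 ± 15 to 16.9 ± 1.05 TPM and Col12a1 from 663 ± 135 to 297 ± 21.6 TPM. Of the matrix proteases and their inhibitors 7 of 21 tested rose, 4 fell and 10 did not pass (7 rose and 6 fell adjusted over the list alone); Ctsk and the inhibitor Timp3 rose with Mmp3 (log2 changes 1.21 and 1.76) and Mmp9 fell by 3.12 on the log2 scale. Their list as a whole did not pass (camera adjusted p = 0.141), and its median was -0.05 as deposited and 0.08 after quantile normalization. Among TGF-beta genes 2 of 20 tested rose, 3 fell and 15 did not pass (2 rose and 4 fell adjusted over the list alone). Ltbp1, which binds latent TGF-beta, rose (log2 change 1.14) and Ctgf, a target of the pathway, fell (log2 change -1.80). The TGF-beta median was -0.15 as deposited and 0.04 after quantile normalization (camera adjusted p = 0.498, with the opposite sign to the median as deposited). The receptor gene Tgfbr2 had 135 ± 19.5 and 149 ± 47.4 TPM and did not pass (adjusted p = 0.742).

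Of the Wnt pathway genes 11 of 26 tested rose and 15 did not pass (13 rose adjusted over the list alone). The Wnt median was 0.72, or 0.92 relative to all tested genes (camera adjusted p = 1.78e-11, and adjusted p = 0.395 with an estimated correlation). Several of the risers encode inhibitors of the pathway. The antagonist gene Dkk2 rose from 2.60 ± 1.21 to 50.5 ± 2.40 TPM and Wif1, another secreted inhibitor, from 0.465 ± 0.304 to 46.6 ± 2.93 TPM, together with the agonist gene Rspo1 (1.93 ± 0.226 to 20.1 ± 6.69 TPM) and the target gene Sp5 (0.12 ± 0.0849 to 10.7 ± 0.297 TPM). Of the BMP pathway genes 6 of 25 tested rose, 4 fell and 15 did not pass (6 rose and 4 fell adjusted over the list alone). The BMP median was 0.15 (camera adjusted p = 0.0256, and adjusted p = 0.527 with an estimated correlation). Bmp4, a ligand that can drive cells towards the adipocyte lineage, rose from 6.42 ± 2.33 to 36.4 ± 12.9 TPM (log2 change 2.33, SE 0.34, adjusted p = 0.00294), Bmp7 rose (log2 change 2.90), and the BMP antagonist gene Grem1 fell (log2 change -1.80). The receptor gene Bmpr1a had 12.8 ± 1.09 and 13.5 ± 1.34 TPM (adjusted p = 0.825, not passed). Of the Hedgehog genes 2 of 10 tested rose and 8 did not pass (5 rose adjusted over the list alone), with the co-receptor gene Cdon among the risers. The Hedgehog median was 0.89 (camera adjusted p = 0.00404, and adjusted p = 0.435 with an estimated correlation).

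Among adipogenic regulators 6 of 22 tested rose, 1 fell and 15 did not pass (6 rose and 1 fell adjusted over the list alone). The adipogenic median was 0.44 (camera adjusted p = 4.76e-05, and adjusted p = 0.395 with an estimated correlation). The risers did not all act alike. Besides Zfp423, the early adipogenic factor Cebpd rose from 105 ± 1.81 to 259.5 ± 64.9 TPM and Klf15 from 1.29 ± 0.0354 to 5.01 ± 0.255 TPM, and Gata3, known as an inhibitor of adipogenesis, rose from 0.15 ± 0.184 to 2.67 ± 0.0495 TPM. Dlk1, which encodes another inhibitor, fell from 48.4 ± 16.8 to 3.72 ± 1.32 TPM. Pparg, the main regulator of adipocyte differentiation, had 4.0 ± 0.785 TPM on day 12 and 7.58 ± 1.05 TPM on day 26 and did not pass (log2 change 0.78, adjusted p = 0.184). Of the genes of mature adipocytes 3 of 19 tested rose, 1 fell and 15 did not pass (3 rose and 1 fell adjusted over the list alone) (median 0.22, camera adjusted p = 0.074). Lpl, the gene of lipoprotein lipase, rose from 133 ± 21.4 to 272 ± 30.9 TPM and the desaturase gene Scd1 from 3.04 ± 0.742 to 12.8 ± 5.15 TPM, while the fatty acid transporter gene Cd36 fell from 21 ± 0.0141 to 3.35 ± 1.29 TPM. Fabp4, the gene of the adipocyte fatty acid binding protein, had 71.1 ± 12 and 63.3 ± 48.4 TPM (adjusted p = 0.63, not passed). Adipoq, which encodes adiponectin, was too low to be tested, with 0.57 and 3.77 TPM in the libraries of day 26 and at most 0.6 TPM in the others, and Cidec, Lep and Ucp1 were listed at 0 in all 8 libraries. Of the brown and beige fat genes 2 of 8 tested rose, 1 fell and 5 did not pass (3 rose and 1 fell adjusted over the list alone) (median 0.80, camera adjusted p = 0.0781), with Prdm16 at 1.07 ± 0.134 and 8.32 ± 2.92 TPM, Elovl3 listed at 0 on day 12 and 2.58 ± 2.06 TPM on day 26, and Kcnk3 as the gene that fell.

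Among inflammatory genes 6 of 20 tested rose, 3 fell and 11 did not pass (6 rose and 3 fell adjusted over the list alone). The inflammatory median was 0.56 (camera adjusted p = 0.000636, and adjusted p = 0.395 with an estimated correlation). The fibroblast chemokine genes Cxcl12 and Cxcl14 rose from 85 ± 3.13 to 296 ± 24.5 TPM and from 7.87 ± 1.23 to 85.8 ± 8.39 TPM, and the macrophage growth factor gene Csf1 from 23.7 ± 0.12 to 58 ± 1.64 TPM. The complement and interferon list split, since 4 of 16 tested rose, 6 fell and 6 did not pass (6 rose and 6 fell adjusted over the list alone). Complement genes rose, among them Serping1 (659 ± 37.7 to 2410.1 ± 86.6 TPM), C1ra and C1s1, and the interferon-induced gene Irf7 fell (199 ± 1.32 to 20.7 ± 12.9 TPM). The median of that list was 0.28, its mean -0.50 and its camera test was upward and did not pass (adjusted p = 0.258). Of the dermal fibroblast lineage genes 5 of 18 tested rose, 1 fell and 12 did not pass (7 rose and 1 fell adjusted over the list alone). The dermal lineage median was 0.58 (camera adjusted p = 4.48e-05, and adjusted p = 0.395 with an estimated correlation). Pi16 and Cd34, markers of fibroblast progenitors, rose from 7.29 ± 4.03 to 139.9 ± 34.4 TPM and from 60.2 ± 28.6 to 321 ± 2.77 TPM. Of the dermal papilla genes 3 of 14 tested rose, 1 fell and 10 did not pass (5 rose and 1 fell adjusted over the list alone). The dermal papilla median was 0.63 (camera adjusted p = 0.00393, and adjusted p = 0.506 with an estimated correlation). Ndnf and the growth factor gene Fgf10 were among the risers and Crabp1 fell, from 2400.1 ± 416 to 1325 ± 25 TPM. Of the genes of dissociation stress 4 of 18 tested fell and 14 did not pass (4 fell adjusted over the list alone), the heat shock genes Hsp90aa1, Hspa8, Hspa1a and Hspa1b (list median 0.06, mean -0.08, camera adjusted p = 0.663).

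Markers of other cell types also moved between these days. Whether genes named above, such as Mmp9, Cd36, Scd1, Elovl3, Gata3 and Bmp7, changed in the labelled cells or with RNA of other cells was not tested. Of the keratinocyte genes 15 of 15 tested rose (15 rose adjusted over the list alone). The keratinocyte marker median was 3.53 (camera adjusted p = 2.09e-19, and adjusted p = 0.395 with an estimated correlation). Krt5, a keratin of basal epidermis, went from 0.175 ± 0.247 through 7.49 ± 4.76 and 24.8 ± 8.42 to 66.5 ± 2.86 TPM, and Krt17 from 0.21 ± 0.0141 to 121 ± 81 TPM. Of the macrophage and leukocyte genes 14 of 19 tested fell and 5 did not pass (1 rose and 15 fell adjusted over the list alone). The macrophage marker median was -1.63 (camera adjusted p = 0.000102, and adjusted p = 0.572 with an estimated correlation). The lysozyme gene Lyz2 went from 2631 ± 752 to 569 ± 248 TPM and Cd68 from 224 ± 65.8 to 24.8 ± 7.23 TPM. Of the erythroid and platelet genes 2 of 7 tested fell and 5 did not pass (3 fell adjusted over the list alone), namely Pf4, which macrophages also express, and Ppbp (camera adjusted p = 0.0426, and adjusted p = 0.619 with an estimated correlation). Of the Schwann cell and melanocyte genes 1 of 12 tested rose and 11 did not pass (none passed adjusted over the list alone), Mlana, listed at 0 on day 12 and 2.50 ± 0.198 TPM on day 26 (list median 0.20, camera adjusted p = 0.16). For endothelial markers none of 14 tested passed in limma, 0 had an unadjusted p under 0.05 (none passed adjusted over the list alone), with a median of 0.24. For pericyte and smooth muscle markers none of 11 tested passed in limma, 1 had an unadjusted p under 0.05 (none passed adjusted over the list alone), with a median of -0.28. For lymphocyte and granulocyte markers none of 7 tested passed in limma, 2 had an unadjusted p under 0.05 (none passed adjusted over the list alone), with a median of -0.17 (0.08 after quantile normalization). For skeletal muscle markers none of 4 tested passed in limma, 0 had an unadjusted p under 0.05 (none passed adjusted over the list alone), too few genes for a list test.

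**Figure D2:**
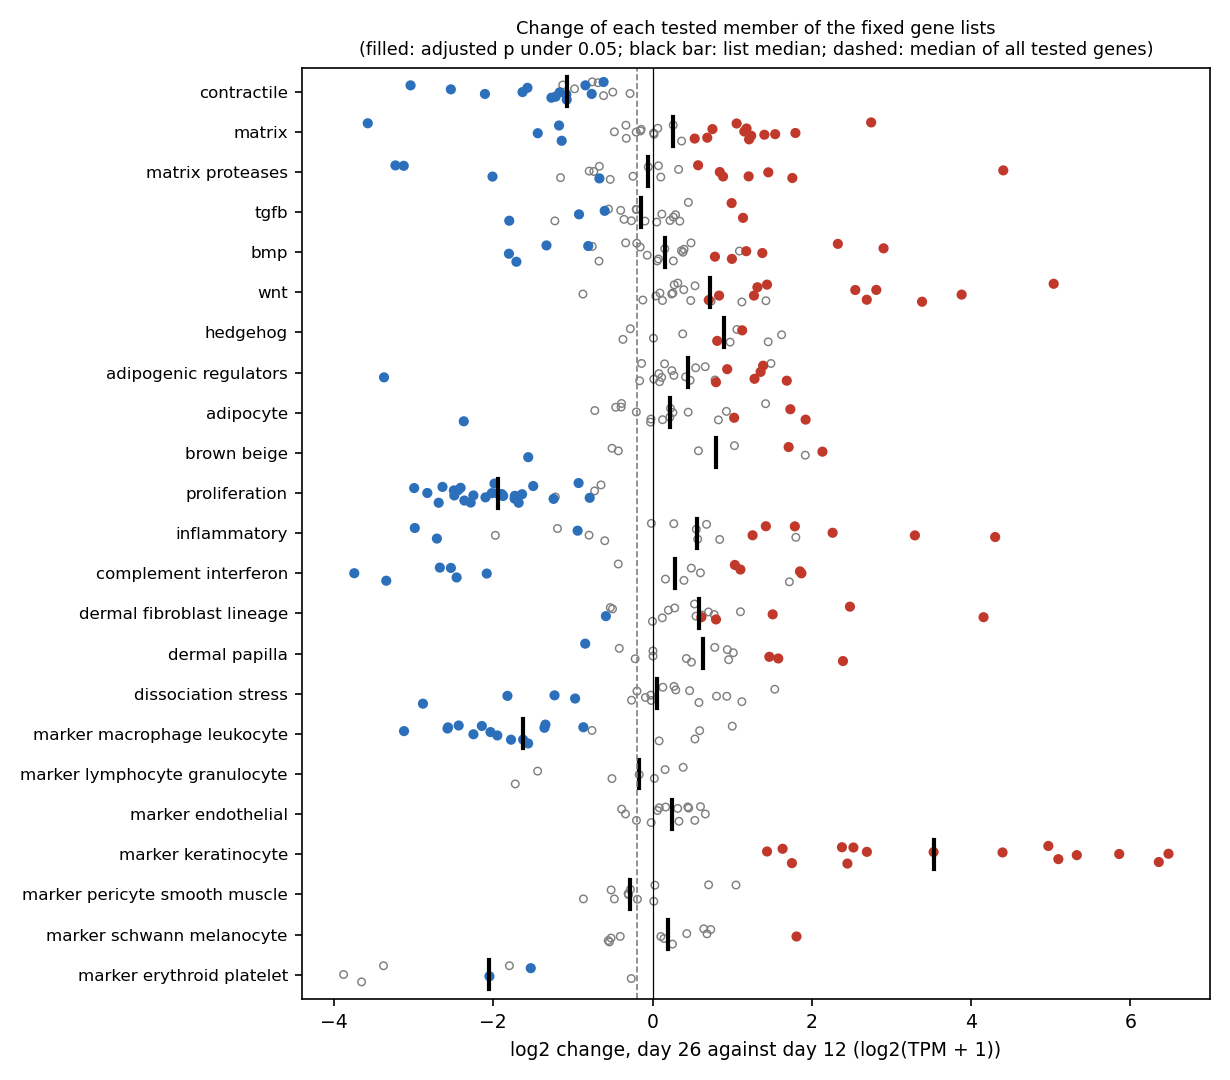
Log2 change from day 12 to day 26 of every tested member of the fixed gene lists with at least 5 tested genes, 1 point per gene, filled where the adjusted p was under 0.05 (red higher, blue lower on day 26). Black bars are list medians, from -2.05 for erythroid and platelet genes to 3.53 for keratinocyte genes, and the dashed line is the median of all tested genes at -0.20.

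In the limma test 2562 of 15062 genes differed between days 12 and 26 at an adjusted p under 0.05, 792 higher and 1770 lower on day 26, and 2494 without the 132 tested marker genes of other cell types. The last count leaves out the listed genes alone and not other RNA of those cell types. Higher genes made up 30.9% of these calls as deposited, 48.9% after quantile normalization and 44.2% after median-ratio scaling, while the median log2 change of all tested genes was -0.20 as deposited, -0.01 after quantile normalization and -0.08 after median-ratio scaling. The number of calls was 718 without library 2 of day 12, 1349 without library 3 of day 12, 1562 without library 1 of day 26 and 1569 without the pair of libraries with the most Xist. Of the 82 gene results of the naming rule in this comparison, 56 passed whichever 1 library was left out. Acta2 and Zfp423 were not among the 56 and passed in 5 of these 8 fits each, Cdon and Elovl3 passed in 3 each and Mlana in 2.

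**Figure D3:**
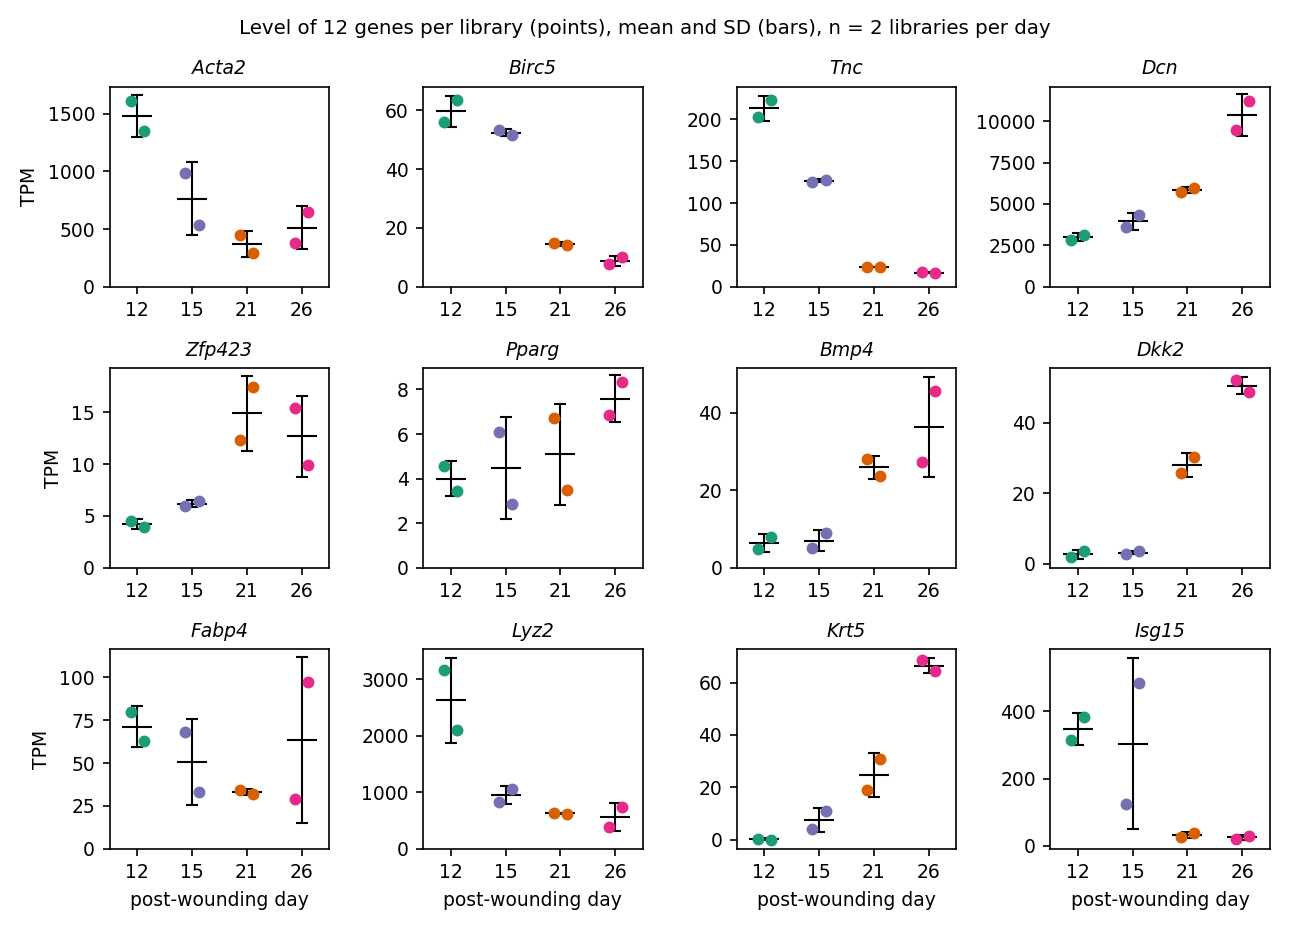
TPM of 12 genes by post-wounding day, 1 point per library, with bars for the mean and SD of the 2 libraries of a day and a separate linear axis per gene. Acta2 had 1481 TPM on day 12 and 513 TPM on day 26, Dkk2 2.60 and 50.5 TPM, and Krt5 0.175 and 66.5 TPM.

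From day 12 to day 15 the largest falls among genes that passed were in Saa3, an acute-phase gene, and Spp1, which encodes the secreted phosphoprotein osteopontin. Spp1 went from 629 ± 313 to 61.1 ± 6.27 TPM (log2 change -3.25, SE 0.30, adjusted p = 0.0313). Saa3 had 592 ± 508 TPM on day 12, a level set mostly by 1 of its libraries, and 8.53 ± 4.08 TPM on day 15 (log2 change -5.70, SE 0.78, adjusted p = 0.0484). The lipid-handling genes Fabp5 and Pla2g7 fell from 976 ± 56.6 to 239 ± 61.2 TPM and from 95.8 ± 14.2 to 28.2 ± 5.76 TPM. Colec11, which encodes a collectin of innate immunity, rose from 2.94 ± 0.658 to 16 ± 3.39 TPM (log2 change 2.10, SE 0.26, adjusted p = 0.0484), followed by the receptor gene Tnfrsf19 (log2 change 1.66), Tmem150c (1.58), Cgref1 (1.43) and C1qtnf7 (1.38).

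By list, 1 of 20 tested fell and 19 did not pass (3 fell adjusted over the list alone) among contractile genes, namely Actg2 (211 ± 9.12 to 82.1 ± 4.59 TPM). The contractile median was -0.42 (camera adjusted p = 1.39e-07, and adjusted p = 0.405 with an estimated correlation). Acta2 had 764 ± 319 TPM on day 15 and did not pass (adjusted p = 0.377). Among inflammatory genes Saa3 fell and Cxcl14 rose from 7.87 ± 1.23 to 20.2 ± 1.95 TPM. The inflammatory median was 0.46 (camera adjusted p = 0.0434, and adjusted p = 0.506 with an estimated correlation). For cell division genes none of 29 tested passed in limma, 0 had an unadjusted p under 0.05 (none passed adjusted over the list alone). The cell division median was -0.25 (camera adjusted p = 0.00027, and adjusted p = 0.676 with an estimated correlation). For Wnt genes none of 26 tested passed in limma, 5 had an unadjusted p under 0.05 (1 rose adjusted over the list alone). The Wnt median was 0.34 (camera adjusted p = 4.28e-05, and adjusted p = 0.395 with an estimated correlation). For Hedgehog genes none of 10 tested passed in limma, 5 had an unadjusted p under 0.05 (none passed adjusted over the list alone). The Hedgehog median was 0.57 (camera adjusted p = 0.00089, and adjusted p = 0.395 with an estimated correlation). For dermal fibroblast lineage genes none of 18 tested passed in limma, 5 had an unadjusted p under 0.05 (5 rose adjusted over the list alone). The dermal lineage median was 0.24 (camera adjusted p = 0.000102, and adjusted p = 0.395 with an estimated correlation). For adipogenic regulators none of 22 tested passed in limma, 4 had an unadjusted p under 0.05 (1 rose adjusted over the list alone). The adipogenic median was 0.30 (camera adjusted p = 0.00836, and adjusted p = 0.506 with an estimated correlation), and Pparg and Zfp423 had log2 changes of 0.08 and 0.46. For matrix genes none of 27 tested passed in limma, 9 had an unadjusted p under 0.05 (2 rose and 1 fell adjusted over the list alone). The matrix median was 0.15 (camera adjusted p = 0.0467, and adjusted p = 0.702 with an estimated correlation), and this list's test turned downward without library 2 of day 12 (adjusted p = 0.487) or without library 3 of day 15 (adjusted p = 0.799).

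Markers of other cell types moved at the same time. Whether Spp1, Fabp5, Pla2g7 and other genes of this step changed in the labelled cells or with RNA of other cells was not tested. Of the keratinocyte genes 1 of 15 tested rose and 14 did not pass (9 rose adjusted over the list alone), Krt5. The keratinocyte marker median was 1.38 (camera adjusted p = 2.27e-11, and adjusted p = 0.395 with an estimated correlation). For macrophage genes none of 19 tested passed in limma, 12 had an unadjusted p under 0.05 (9 fell adjusted over the list alone). The macrophage marker median was -0.98 (camera adjusted p = 3.87e-14, and adjusted p = 0.395 with an estimated correlation), Lyz2 at 949 ± 159.6 TPM and Cd68 at 72.9 ± 26 TPM on day 15. The medians of the Schwann cell and melanocyte list and of the erythroid and platelet list were 1.14 (camera adjusted p = 0.000373, and adjusted p = 0.455 with an estimated correlation) and -1.92 (camera adjusted p = 3.39e-05, and adjusted p = 0.395 with an estimated correlation). In all, 24 genes passed between days 12 and 15, 13 higher and 11 lower on day 15, and 1316 had an unadjusted p under 0.05. The number of calls was 1 without library 2 of day 12, 2 without library 3 of day 12, 18 without library 3 of day 15 (1 higher and 17 lower), 0 in limma without library 1 of day 15 (890 at an unadjusted p under 0.05), 0 without library 2 of day 21 (1188) or library 3 of day 21 (1191), 49 without library 1 of day 26, 50 without library 2 of day 26, and 0 without the pair of libraries with the most Xist (796). It was 4 after quantile normalization and 4 after median-ratio scaling, with 25% of those calls higher on day 15 against 54.2% as deposited and 74.2% of 31 calls with a pseudocount of 0.1, and none of the 12 gene results of the naming rule passed in every fit that left out 1 library.

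From day 15 to day 21 the 2 tenascin genes, Isg15, Irf7 and Rtp4 fell, and Dkk2, Cyp2f2 and Wisp2 rose. Tnc went from 127 ± 1.67 to 23.5 ± 0.346 TPM (log2 change -2.38, SE 0.14, adjusted p = 0.000625) and Tnn from 106 ± 31.3 to 9.54 ± 2.63 TPM (log2 change -3.33, SE 0.29, adjusted p = 0.00629). The interferon-induced genes Isg15, Irf7 and Rtp4 fell from 304 ± 254 to 33 ± 8.86 TPM, with a wide spread on day 15, from 152 ± 81.7 to 23.3 ± 1.89 TPM and from 84.2 ± 32.6 to 15.8 ± 1.48 TPM. Dkk2 rose from 3.13 ± 0.537 to 28 ± 3.34 TPM (log2 change 2.81, SE 0.26, adjusted p = 0.00781), Cyp2f2 from 13.2 ± 8.0 to 124 ± 32 TPM and Wisp2 from 107 ± 43.5 to 688 ± 133 TPM. The neuropeptide gene Gal rose from 11.1 ± 4.80 to 44.9 ± 6.36 TPM, and Igfbp2, which encodes a binding protein of insulin-like growth factors, from 2664 ± 1073 to 9688 ± 2905 TPM.

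Of the cell division genes 11 of 29 tested fell and 18 did not pass (28 fell adjusted over the list alone). The cell division median was -1.33 (camera adjusted p = 1.4e-19, and adjusted p = 0.395 with an estimated correlation). Birc5 went from 52.4 ± 1.14 to 14.5 ± 0.594 TPM, Top2a, a topoisomerase gene of dividing cells, from 21.5 ± 4.60 to 5.46 ± 1.01 TPM, and the mitotic kinase gene Aurka from 13.9 ± 0.898 to 3.10 ± 0.919 TPM. Of the contractile genes 2 of 20 tested fell and 18 did not pass (9 fell adjusted over the list alone), Actg2 and Tpm2. The contractile median was -0.57 (camera adjusted p = 2.07e-05, and adjusted p = 0.473 with an estimated correlation). Acta2 had 764 ± 319 and 370.3 ± 111 TPM (adjusted p = 0.167, not passed). Of the complement and interferon genes 1 of 16 tested rose, 3 fell and 12 did not pass (1 rose and 7 fell adjusted over the list alone). Serping1 was the gene that rose, and Isg15 and Irf7 were among those that fell. The complement and interferon median was -0.45 (camera adjusted p = 0.0254, and adjusted p = 0.506 with an estimated correlation). Of the matrix genes 1 of 27 tested fell and 26 did not pass (7 rose and 3 fell adjusted over the list alone), with Tnc as the gene that fell and a median of 0.24 (camera adjusted p = 0.00929, and adjusted p = 0.7 with an estimated correlation). Of the matrix proteases 1 of 21 tested rose and 20 did not pass (3 rose and 1 fell adjusted over the list alone), Mmp3 (median 0.06, camera adjusted p = 0.2).

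Signalling genes rose in small numbers. Of the Wnt genes 2 of 26 tested rose and 24 did not pass (6 rose adjusted over the list alone), Dkk2 and Tcf7l2. The Wnt median was 0.13 (camera adjusted p = 0.00132, and adjusted p = 0.435 with an estimated correlation). Of the BMP genes 1 of 25 tested rose and 24 did not pass (1 rose adjusted over the list alone), Bmp4, from 6.96 ± 2.72 to 25.9 ± 2.99 TPM (log2 change 1.80, SE 0.34, adjusted p = 0.0449). Of the TGF-beta genes 1 of 20 tested rose and 19 did not pass (2 rose and 1 fell adjusted over the list alone), Ctgf, from 12.1 ± 0.00707 to 38.6 ± 12 TPM. In the step before, from day 12 to day 15, Ctgf had a log2 change of -1.40 (limma adjusted p = 0.115, not passed). The TGF-beta median was 0.29 (camera adjusted p = 0.00027, and adjusted p = 0.395 with an estimated correlation). Of the inflammatory genes 1 of 20 tested rose and 19 did not pass (5 rose adjusted over the list alone), Cxcl14. The inflammatory median was 0.68 (camera adjusted p = 5.6e-05, and adjusted p = 0.395 with an estimated correlation). Of the adipogenic regulators 1 of 22 tested fell and 21 did not pass (1 rose and 1 fell adjusted over the list alone), Dlk1, from 33.3 ± 12.4 to 7.36 ± 1.90 TPM. The adipogenic median was 0.20 (camera adjusted p = 0.0266, and adjusted p = 0.572 with an estimated correlation). Zfp423 had 6.18 ± 0.346 TPM on day 15 and 14.9 ± 3.63 TPM on day 21 and did not pass (log2 change 1.13, adjusted p = 0.0828). Fgf7, a growth factor gene of the dermal papilla list, and Jund, of the dissociation stress list, each rose as the single member of its list past the test (log2 changes 1.61 and 1.20). Between days 12 and 15 Fgf7 had a log2 change of -1.55 (limma adjusted p = 0.102, not passed). For Hedgehog genes none of 10 tested passed in limma, 3 had an unadjusted p under 0.05 (none passed adjusted over the list alone). The Hedgehog median was 0.37 (camera adjusted p = 0.0312, and adjusted p = 0.53 with an estimated correlation).

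Of the keratinocyte markers 1 of 15 tested rose and 14 did not pass (3 rose adjusted over the list alone), Krt15. The keratinocyte marker median was 0.86 (camera adjusted p = 0.000261, and adjusted p = 0.441 with an estimated correlation). The median of the macrophage markers was 0.02 (camera adjusted p = 0.141), that of the pericyte and smooth muscle markers -0.96 (camera adjusted p = 0.0105, and adjusted p = 0.684 with an estimated correlation), and that of the lymphocyte and granulocyte markers 0.22 (camera adjusted p = 0.0257, and adjusted p = 0.395 with an estimated correlation). In all, 211 genes passed between days 15 and 21, 74 higher and 137 lower on day 21. The number was 37 without library 2 of day 12, 37 without library 3 of day 12, 78 without library 1 of day 15 (21 higher and 57 lower), 57 without library 3 of day 15 (39 higher and 18 lower), 4 without library 2 of day 21 and 2 without library 3 of day 21 (all lower), 321 without library 2 of day 26, and 0 in limma without the pair of libraries with the most Xist (1502 at an unadjusted p under 0.05). Higher genes were 35.1% of the calls as deposited, 48.4% after quantile normalization and 55.4% after median-ratio scaling, and of the 27 gene results of the naming rule 1, that of Tnc, passed whichever 1 library was left out.

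From day 21 to day 26 Mmp3 rose again and Ctgf and the imprinted RNA Meg3 fell. Mmp3 went from 565 ± 96.7 to 2015 ± 252 TPM (log2 change 1.84, SE 0.25, adjusted p = 0.0421). Efemp1, which encodes the matrix protein fibulin-3, rose from 83.9 ± 1.60 to 211 ± 32.1 TPM, Btg3, an inhibitor of proliferation, from 7.22 ± 1.09 to 22.3 ± 1.76 TPM, the interferon-inducible GTPase gene Iigp1 from 11.7 ± 2.36 to 31.7 ± 5.0 TPM, and the lectin receptor gene Cd302 from 174 ± 10.2 to 341 ± 0.424 TPM. Ctgf went from 38.6 ± 12 to 9.26 ± 3.40 TPM (log2 change -1.95, SE 0.28, adjusted p = 0.0447) and Meg3 from 1512 ± 42.3 to 398 ± 4.56 TPM (log2 change -1.92, SE 0.29, adjusted p = 0.0466). The genes AY036118, RP24-317P24.2 and Gp49a, a leukocyte receptor gene, fell as well (log2 changes -3.06, -2.26 and -1.75).

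Most fixed lists had few or no single genes past the test at this step. Of the lymphocyte and granulocyte markers 2 of 7 tested fell and 5 did not pass (2 fell adjusted over the list alone), the mast cell protease genes Cpa3 (23.8 ± 8.0 to 1.5 ± 0.785 TPM) and Mcpt4 (55.7 ± 23.4 to 4.22 ± 3.98 TPM). The lymphocyte marker median was -0.71 (camera adjusted p = 0.016, and adjusted p = 0.395 with an estimated correlation). For Wnt genes none of 26 tested passed in limma, 9 had an unadjusted p under 0.05 (4 rose and 1 fell adjusted over the list alone). The Wnt median was 0.36 (camera adjusted p = 0.000539, and adjusted p = 0.405 with an estimated correlation). For complement and interferon genes none of 16 tested passed in limma, 6 had an unadjusted p under 0.05 (1 rose adjusted over the list alone). The complement and interferon median was 0.36 (camera adjusted p = 0.000473, and adjusted p = 0.395 with an estimated correlation). For genes of dissociation stress none of 18 tested passed in limma, 7 had an unadjusted p under 0.05 (1 fell adjusted over the list alone). The stress median was -0.91 (camera adjusted p = 0.000511, and adjusted p = 0.572 with an estimated correlation). For cell division genes none of 29 tested passed in limma, 6 had an unadjusted p under 0.05 (3 fell adjusted over the list alone). The cell division median was -0.45 (camera adjusted p = 0.0194, and adjusted p = 0.702 with an estimated correlation). For keratinocyte markers none of 15 tested passed in limma, 14 had an unadjusted p under 0.05 (14 rose adjusted over the list alone). The keratinocyte marker median was 1.65 (camera adjusted p = 8.73e-14, and adjusted p = 0.395 with an estimated correlation), with Krt17 at 16 ± 3.57 and 121 ± 81 TPM (adjusted p = 0.0575, not passed). The medians of the macrophage list and of the pericyte list were -0.74 (camera adjusted p = 0.00278, and adjusted p = 0.684 with an estimated correlation) and 0.67 (camera adjusted p = 0.00596, and adjusted p = 0.684 with an estimated correlation). Contractile and matrix genes had medians of -0.03 and -0.06 and no list call (camera adjusted p = 0.618 and 0.968). Acta2 had 370.3 ± 111 and 513 ± 186 TPM (log2 change 0.45, not passed), Bmp4 25.9 ± 2.99 and 36.4 ± 12.9 TPM, and Pparg 5.08 ± 2.28 and 7.58 ± 1.05 TPM (adjusted p = 0.47, not passed).

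In all, 48 genes passed between days 21 and 26, 15 higher and 33 lower on day 26. The number was 31 without library 2 of day 12, 31 without library 3 of day 12, 17 without library 1 of day 15, 17 without library 3 of day 15, 0 in limma without library 2 of day 21 (1827 at an unadjusted p under 0.05) or library 3 of day 21 (1995), 24 without library 2 of day 26 (all lower), and 0 without the pair of libraries with the most Xist (2044). Higher genes were 31.2% of the calls as deposited, 46.7% after quantile normalization, 31.4% after median-ratio scaling and 22.8% for protein-coding genes alone, and none of the 12 gene results of the naming rule passed in every fit that left out 1 library. Whether a gene's change differed between one step and the next was not tested.

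Over all 4 days together, 1866 genes passed limma's F test, 1808 of them outside the listed marker genes of other cell types, a count that does not remove other RNA of those cells. The authors' tables place 4120 genes in 5 clusters, each gene with a p-value of the authors, and 3563 of these genes were among those tested here. Of the 1866 genes, 1522 (81.6%) were in a cluster. The authors formed the clusters on these libraries, so the direction of a cluster is not independent evidence. Tested genes of C1 had mean log2 levels, relative to each gene's own mean, of 0.57, 0.19, -0.42 and -0.35 on days 12, 15, 21 and 26, and those of C2 of 0.46, 0.27, -0.12 and -0.61. Genes of C3 were highest on day 21 (0.44), genes of C4 were low on day 12 (-0.75) and high on days 21 and 26 (0.41 and 0.54), and genes of C5 were highest on day 26 (0.72). In C1, 582 of 1165 tested genes fell between days 12 and 26, and in C2 796 of 1187. In C4 443 of 652 and in C5 161 of 286 rose.

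The fixed lists fell unevenly over the clusters in Fisher's exact test against the tested genes, with 115 pairs of list and cluster. That test takes genes as independent, whereas genes of a list vary together (estimated correlation 0.581 for cell division and 0.577 for matrix genes). The clusters were also formed on these libraries, so the p-values are likely too small. Cell division genes were in C1 (14 of 29, adjusted p = 4.78e-07) and C2 (14 of 29, adjusted p = 4.78e-07), and contractile genes in C1 (9 of 20, adjusted p = 0.000212). C4 held 10 of 27 matrix genes (adjusted p = 3.57e-06), 7 of 20 inflammatory genes (adjusted p = 0.0003), 7 of 26 Wnt genes (adjusted p = 0.00145) and 6 of 21 matrix proteases (adjusted p = 0.00287). Keratinocyte markers were in C4 (6 of 15, adjusted p = 0.000441) and C5 (3 of 15, adjusted p = 0.0333). The authors' own gene ontology marks gave 84 genes of C1 and 122 of C2 the term cell cycle, and 41 genes of C4 the term matrix. The number of genes past the F test was 570 without library 2 of day 12, 790 without library 3 of day 12, 867 without library 2 of day 21, 840 without library 3 of day 21 and 276 without the pair of libraries with the most Xist.

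**Figure D4:**
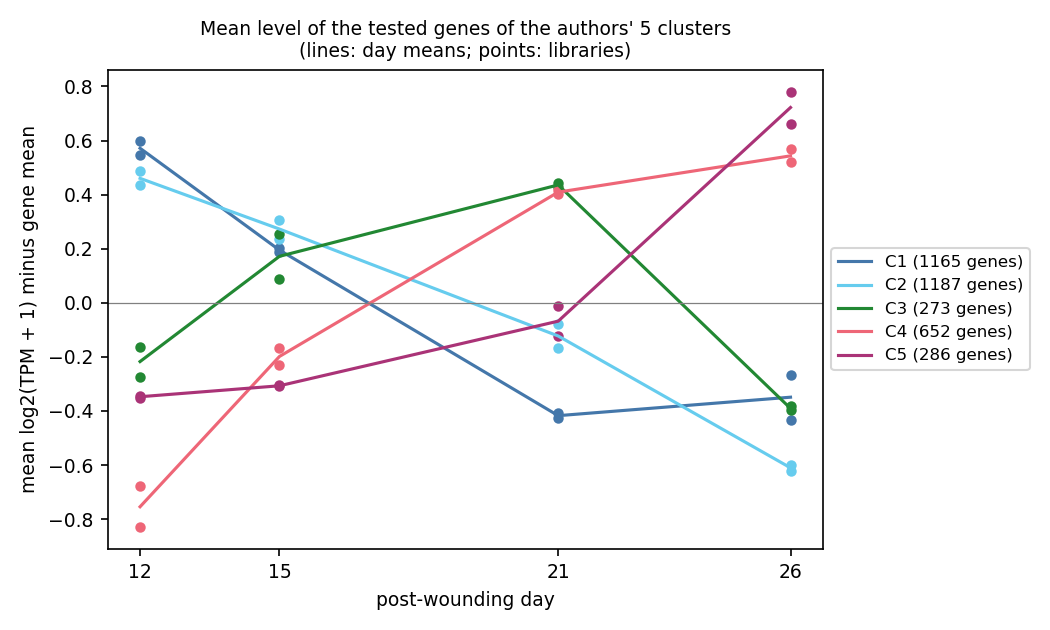
Mean log2(TPM + 1) relative to each gene's own mean, by post-wounding day, for the tested genes of the authors' 5 clusters, with lines through the day means and 1 point per library. C1 went from 0.57 on day 12 to -0.35 on day 26 and C4 from -0.75 to 0.54, and the clusters were formed on these libraries.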

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

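Chosen only after the results were seen were median-ratio scaling, protein-coding genes alone, leaving out the pair of libraries with the most Xist, the Xist and Y-linked covariates, and the block on column number. Of the genes that passed as deposited, every one kept its sign in each alternative in which it was present, and of the 133 gene results of the naming rule none reversed. Of these 133, 58 no longer passed with no filter, 55 from the 2 days alone, 61 without the libraries with the most Xist, 47 with the block, 40 and 39 with the Xist and Y-linked covariates, 21 after quantile normalization, 18 after median-ratio scaling, 16 with a pseudocount of 0.1, 11 with sample weights, and 18 to 60 when 1 library was left out. The count of genes between days 12 and 26 was 1667 with no filter on low values (more genes tested), 1569 without the libraries with the most Xist and 1590 from the 2 days alone (fewer samples). The count between days 12 and 15 was 4 after quantile normalization, 3 with no filter, 4 after median-ratio scaling, 39 for protein-coding genes alone, and 0 in limma without the libraries with the most Xist, with the Xist covariate, with the Y-linked covariate and from the 2 days alone (796, 450, 705 and 1334 at an unadjusted p under 0.05). The count between days 15 and 21 was 134 with a pseudocount of 0.1, 44 with no filter, 74 with the Xist covariate, 56 with the Y-linked covariate, 16 from the 2 days alone, and 0 without the libraries with the most Xist (1502 unadjusted). The count between days 21 and 26 was 15 with a pseudocount of 0.1, 10 with no filter, 26 with a filter at 10 TPM, 14 with sample weights, 101 for protein-coding genes alone, 6 with the Y-linked covariate, 4 from the 2 days alone, and 0 without the libraries with the most Xist and with the Xist covariate (2044 and 798 unadjusted). The F test over the 4 days gave 781 genes with no filter, 276 without the libraries with the most Xist and 1014 with the Xist covariate. The brackets on genes tested and on samples name how a setting differs. The cause of a difference in counts was not tested for any setting. Leaving out 1 library gave 718 to 2538 genes between days 12 and 26, 0 to 50 between days 12 and 15 (0 in limma, with 890 unadjusted, without library 1 of day 15, and 50 without library 2 of day 26), 2 to 321 between days 15 and 21, 0 to 71 between days 21 and 26 (0 with 1827 unadjusted without library 2 of day 21), and 570 to 1822 in the F test. In contrasts that do not hold the library left out, the fit has fewer samples for its spread. The fits without the libraries with the most Xist kept 1 library on day 15 and 1 on day 21. No other pair was left out for comparison, so their counts do not show an effect of Xist or sex.

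Of the 92 list tests 45 passed, 42 to 52 when 1 library was left out, and 0 in camera with an estimated correlation. Of the 45, those lost were 6 after quantile normalization (matrix between days 12 and 15, 15 and 21, and 12 and 26, complement and interferon and lymphocyte markers between days 15 and 21, and cell division between days 21 and 26), 3 after median-ratio scaling, 3 with no filter, 2 for protein-coding genes alone and 4 with the block, and 38 to 43 were kept when 1 library was left out. The matrix list between days 12 and 15 reversed without library 2 of day 12 (adjusted p = 0.487) and without library 3 of day 15 (adjusted p = 0.799), against 1.59e-05 without library 3 of day 12 as the lowest, and the cause was not tested. Of the pairs of list and cluster, 24 passed with all genes of the table as background, where genes that could not be tested count as background, against 9 as reported. The mean r within a day was 0.877 over the 1000 most variable genes and 0.949 with a pseudocount of 0.1, against 0.692 and 0.915 between days, the former over genes picked for their spread. The samples could not be paired by the labels, whose replicate numbers are not those of the columns, and any 2 days compared share 1 column number. A replicate block on the column number over all 8 libraries, with 2 residual degrees of freedom, gave 1474 genes between days 12 and 26, 1 between days 12 and 15, 83 between days 15 and 21, 0 in limma between days 21 and 26 (2524 unadjusted), 1087 in the F test and 52 list tests. Deviations from the day means of libraries with the same number correlated at -0.23 to 0.14, so the numbers showed no pairing. The alternatives planned for counts (DESeq2 and its size factors) were not run because the values are TPM plus 1. No group held 3 samples or more, so other splits of the samples could not be counted.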

Other observations

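Among the tests and lists below, the added lists, the second keratinocyte and leukocyte lists, the macrophage list as a measure of purity, median-ratio scaling, protein-coding genes alone, and the Xist and Y-linked covariates were chosen only after results were seen. The imprinted, ribosomal, glycolysis, cholesterol and GTPase lists were drawn up from values already seen, so no list test is given for them. For the same reason, their counts adjusted over the list alone describe genes picked for their values. Those counts are no evidence that a list changed. Of the imprinted genes 11 of 16 tested fell and 5 did not pass (11 fell adjusted over the list alone) between days 12 and 26, with a median log2 change of -1.15. Besides Mest, H19 and Igf2, these were Dlk1, Nnat, Slc38a4, Plagl1, Cdkn1c, Meg3, Grb10 and Igf2r, the receptor that clears Igf2 protein (20.4 ± 2.36 to 9.14 ± 1.37 TPM), while the imprinted genes Ndn (113 ± 7.16 and 117 ± 5.35 TPM) and Peg3 (33.5 ± 10.3 and 24.7 ± 10.2 TPM) did not pass. Of the ribosomal protein genes 55 of 79 tested fell and 24 did not pass (66 fell adjusted over the list alone) between days 12 and 26, with a median of -0.65, -0.53 after quantile normalization and -0.51 after median-ratio scaling. Rpl3, for example, went from 510.2 ± 71 to 188 ± 19.1 TPM, and with protein-coding genes alone, from which pseudogenes are left out, the median was -0.70. That setting drops the TPM of pseudogenes and does not return them to parent genes, so it does not test whether reads were shared. Of the genes of glycolysis 7 of 15 tested fell and 8 did not pass (7 fell adjusted over the list alone), among them Gapdh (1102 ± 27.7 to 584 ± 42.2 TPM) and Pkm (461 ± 41.2 to 289 ± 8.53 TPM), with a median of -0.57. Of the genes of cholesterol metabolism 4 of 16 tested rose and 12 did not pass (5 rose adjusted over the list alone), with Insig1 (19.1 ± 3.05 to 53.6 ± 18.7 TPM), Msmo1 and Sc5d among the risers and a median of 0.54.

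Of the interferon-inducible GTPases, which act against pathogens inside cells, 7 of 13 tested fell and 6 did not pass (12 fell adjusted over the list alone) between days 15 and 21, with a median of -1.31. Gbp3 went from 60.1 ± 19 to 14 ± 2.48 TPM, Igtp from 49.7 ± 15 to 16.8 ± 2.39 TPM and Iigp1 from 56.6 ± 6.65 to 11.7 ± 2.36 TPM, and Iigp1 was the single gene of the list that rose from day 21 to day 26. From day 12 to day 26, 6 of 13 tested fell and 7 did not pass (7 fell adjusted over the list alone), with a median of -0.76. The Y-linked gene Ddx3y had 26.8 and 24.8 TPM in the libraries of day 12, 0 and 23.9 TPM on day 15, 24.5 and 7.43 TPM on day 21, and 34.0 and 30.0 TPM on day 26. Library 1 of day 15 thus held Xist and no Ddx3y, and library 3 of day 15 and both libraries of day 21 held Xist and Ddx3y. For the Y-linked list between days 12 and 26, none of 4 tested passed in limma, 0 had an unadjusted p under 0.05 (none passed adjusted over the list alone), with a median of -0.01 as deposited, 0.21 after quantile normalization and 0.11 after median-ratio scaling. Its median was -1.999 from day 12 to day 15 (0 of 4 genes above 0, 2 with an unadjusted p under 0.05 and none passed in limma), 1.27 from day 15 to day 21 and 0.49 from day 21 to day 26 (4 of 4 above 0 and none passed in both).

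Keratinocyte transcripts rose from day 12 to day 26 in all 15 tested markers, 2 of which averaged 1 TPM or more on day 12. A fall in the purity of the sort that let in every other cell type alike would raise their markers together. The macrophage list went the other way, with a median of -1.625, and the endothelial list had a median of 0.24. This expectation was set down after the macrophage values were seen. The mix of cells in the wound on each day was not measured, so these values do not exclude a less pure sort. A candidate explanation is epithelial RNA in the later sorts, although the viable tdTomato-high gate should remove cells without the label, and a second keratinocyte list gave a median of 2.441 with 84.2% of its 19 genes above 0 (13 rose, 1 fell and 5 did not pass, and its member Lgals7 was already among the largest rises). The most abundant markers on day 26 were Krt14 at 189 ± 92 TPM, Krt17 at 121 ± 81 TPM and Krt5 at 66.5 ± 2.86 TPM, 8 of the 19 genes averaged 1 TPM or more on day 12, none is in another list, and 9 are in the authors' clusters, as are 9 of the first 15. Transcription of these genes in the sorted cells themselves was not tested and stays open.

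Macrophage transcripts fell from day 12 to day 26 in 14 of 19 tested markers. Scaling of the deposited values does not account for this, since the median was -1.515 after median-ratio scaling. A candidate explanation is less leukocyte RNA in the later sorts, either from cells inside the viable tdTomato-high gate or taken up by them, and a second leukocyte list gave a median of -1.844 with 95.8% of its 24 genes below 0 (21 fell, 1 rose and 2 did not pass). Lyz2 still had 569 ± 248 TPM on day 26, and Csf1r (64.9 ± 15.6 and 67.8 ± 1.34 TPM), H2-Ab1 (194 ± 26 and 393 ± 96.4 TPM) and Cd74 (501 ± 83.5 and 725 ± 126 TPM) did not pass, so the markers did not move alike. Of the 24 genes all averaged 1 TPM or more on day 12, none is in another list and 14 are in the authors' clusters, as are 10 of the first 19, and a change in the myeloid genes of the labelled cells was not tested and stays open.

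The 211 genes that passed between days 15 and 21 were set against the sex of the animals behind the libraries, since Xist differed within both days, with mean log2 levels of 3.85 on day 15 and 3.68 on day 21, whereas the mean log2 level of 4 Y-linked genes was 1.89 and 3.26. The median ratio of the log2 changes of the 211 genes with and without a covariate was 1 with the Xist level and 1.004 with the Y-linked level (quartiles 0.928 and 1.07), with a median size of the changes of 1.52 without a covariate (median SE 0.24), 1.54 with Xist (SE 0.24) and 1.52 with the Y-linked level (SE 0.28), and 68 and 38 of the 211 genes still passed, with 3 residual degrees of freedom in place of 4. The mean log2 level of Xist differed by only -0.17 between these days, so its covariate could hardly move a change. The ratio with Xist therefore does not bear on sex. Genes that pass have small differences within a day, which favours ratios near 1. Their median was 0.16 between the libraries with more and less Xist, averaged over both days. Over the 878 genes with a log2 change of at least 1 in size, taken whatever their p, the ratio with the Y-linked level was 0.959 (quartiles 0.815 and 1.11). These genes were taken by the same change that the ratio divides by, and 173 of them had passed. The Y-linked level differed by 3.15 between the libraries of day 15 and by 1.27 between those of day 21. The covariate thus leaned most on day 15, and the ratio does not decide whether sex was a cause. A change of the sorted cells with time, which the design names, stays open, as does sex. Other differences between the animals were not tested and stay open too. From day 12 to day 15 and from day 21 to day 26 Xist changed along with the day, so sex and day could not be told apart. In limma no gene passed in those steps with the Xist covariate (450 and 798 at an unadjusted p under 0.05).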
